A study of Mus musculus with 6 samples.

How the data were processed

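Total RNA of bone marrow-derived macrophages from vimentin-deficient mice and wild-type littermates, 3 biological replicates per genotype, was hybridised, 1 sample per array, to Affymetrix mouse whole-genome expression arrays. Per the labels, femoral marrow was plated in high-glucose medium with the supernatant of a cell line that secretes mouse macrophage colony-stimulating factor, RNA was extracted with Trizol, and biotin-labelled cRNA was made by the manufacturer's protocol. The mice were 17 weeks old on a C57BL/6 background. Group and replicate number were taken from the sample titles.

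The values used are the log2 probe set values the authors deposited in the series table. The summary and normalization method behind them is not given in the sources used here. From the values themselves, the scale is log2, running from 5.43 to 14.50, and the 6 array medians lie between 7.23 and 7.25. Because the medians lay within 0.1 of each other, the values were used as deposited. Background signal cannot be separated from these values, so folds of dim genes, and the low side of the Vim fold, can be compressed.

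The table held 45101 probe sets, 64 of them controls. In the platform annotation 34945 probe sets named 1 gene symbol, 932 named several and 9160 had no symbol there. Of the probe sets with 1 symbol, 34741 were matched to a mouse gene table (assembly GRCm38.p6) by Entrez ID to update symbols. No genome build is named for the array values, so that table served only for names and for which genes lie near each other. A gene was represented by its probe set with the highest mean over the 6 arrays, which gave 18193 genes. Genes whose mean lay at or above the 40th percentile of all non-control probe sets, 6.93, were tested, which left 13445. Of these, 5791 had several probe sets above that value. Of the named genes, 76 had several, and 14 of them had 1 or more probe sets of opposite sign, among them Ighm, Msr1, Fabp4, Atf4, Abcg1 and Irf8.

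Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), vimentin-deficient against wild-type, without covariates. P-values were adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. Standard errors use the moderated variance of limma, and SDs are between arrays. Gene lists were tested with camera at its preset correlation between genes of 0.01, with camera at a correlation estimated from the data, and with fry in its directional and mixed versions. The 39 lists with at least 4 tested genes were adjusted together. All lists and the rule for named genes were fixed before the data were examined, as were most alternative settings. Those chosen afterwards were the comparison of genes near Vim without vimentin-deficient replicate 3 and with array quality weights, for RNA quality both other normalizations and the Tfrc and Pcx control probe sets, and the estimated correlation and fry in the fits without 1 array. The fit without vimentin-deficient replicate 3 was among the alternatives fixed beforehand, but the closer description of it, with its own named genes and splits, was chosen after seeing that this array stood apart.

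The rule for named genes took Vim, then the 12 largest rises and the 12 largest falls past the threshold with no overlap between groups. If fewer than 5 passed in a direction, the 10 with the smallest p were added and described as not passing. It also took up to 4 members with the smallest p from each described list, the 2 brightest members of each list of cell type markers, and 14 fixed read-outs of macrophages in atherosclerosis. Uncharacterised clones were skipped. Of the 14 read-outs, 11 were tested and the rest are not analysed here. Genes named outside the rule were chosen after their values were seen. These are the examples of vimentin-deficient replicate 3, the genes near Vim, Spaca9, Scarb1, Ifit1, Ifit2, Ifit3, Irf7 and Irf1 in the interferon list with 6 arrays, the list members given for the fit without that array, and the genes of the split of wild-type replicates 2 and 3 against the rest.

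The procedure was tested on simulated data with the real means and variances drawn from the fitted prior. With 6 arrays over 13445 genes, 53.7% of genes changed 1.5-fold, 94.0% of those changed 2-fold and 92.4% of those changed 4-fold were recovered, and 13 of 13245 unchanged genes were called. Without vimentin-deficient replicate 3 the shares were 95.5%, 100.0% and 100.0%, with 9 unchanged genes called. In both, camera called the 1 list that had been shifted. The simulated noise was independent between genes and arrays, and no simulated array stood apart. These shares need not carry over to the real arrays, where 1 array stands apart and genes of a list move together.

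Alternatives covered quantile normalization, median centring, the filter, the rule for several probe sets, the variance model, array quality weights, a per-gene test, the replicate number as a block, the thresholds, the window around Vim, and each array left out in turn. Probe sets without a symbol in the annotation were tested separately: 4026 were above the filter, 0 passed with 6 arrays, where 222 had an unadjusted limma p under 0.05, and without vimentin-deficient replicate 3 there were 23 higher and 12 lower. RNA quality was read from the 3' and 5' control probe sets with an exact two-sided permutation test.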

Results

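RNA from bone marrow-derived macrophages of vimentin-deficient mice and of wild-type littermates was measured on Affymetrix mouse expression arrays, with 3 arrays per genotype. Vimentin is the intermediate filament protein of mesenchymal and myeloid cells. The animals were 17 weeks old on a C57BL/6 background, and the marrow was cultured with macrophage colony-stimulating factor at normal oxygen. The labels call the 3 samples of each genotype biological replicates, so each is taken as a separate animal or culture. Each array gave 45101 probe set values on the log2 scale, with array medians between 7.23 and 7.25. The number of arrays, 3 per genotype, limits the precision of every comparison.

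Vim itself was lower on all 3 vimentin-deficient arrays. The brightest of its 3 probe sets read 7.43 ± 0.67 (SD, n = 3) in vimentin-deficient and 13.32 ± 0.09 (SD, n = 3) in wild-type macrophages, a 59.4-fold difference (log2 fold change -5.89, SE 0.31, limma adjusted p = 0.00414 with Benjamini-Hochberg). The other two probe sets differed 42.2-fold and 54.6-fold. Among the vimentin-deficient arrays, replicate 1 read highest on this probe set, at 8.20, against 6.96 for replicate 2 and 7.13 for replicate 3. The limma adjusted p of Vim was 0.0527, 0.0501 and 0.0766 without wild-type replicates 1, 2 and 3, while its log2 fold change stayed between -6.28 and -5.66 in the 6 fits without 1 array.

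**Figure D1:**
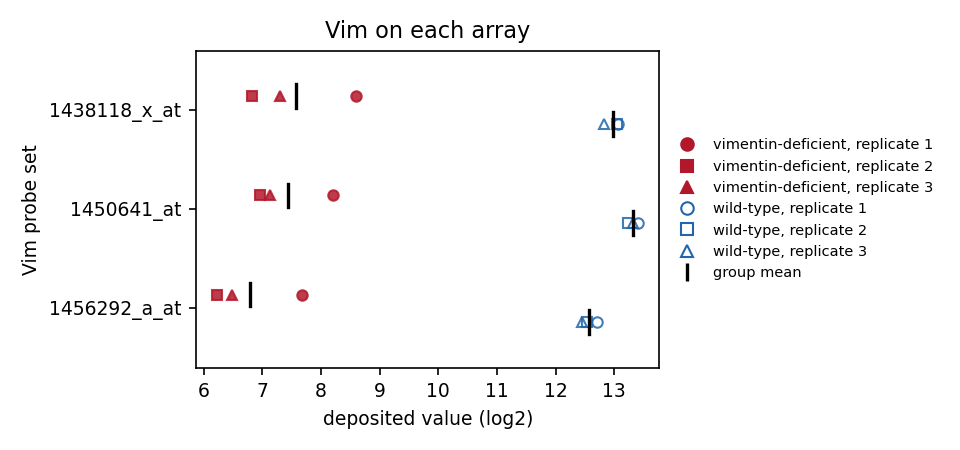
Deposited log2 value of the 3 Vim probe sets on each of the 6 arrays (points) with the mean of each genotype (vertical bars). On every probe set the 3 vimentin-deficient arrays lie at least 4.22 log2 units below the lowest wild-type array.

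The series design names the role of vimentin in atherosclerosis after transplantation of vimentin-deficient marrow, and the first question was which transcripts differed between the genotypes. With all 6 arrays, 3 of 13445 genes fell in vimentin-deficient macrophages and 0 rose. Besides Vim these were Ak8, which encodes an adenylate kinase (log2 fold change -0.88, SE 0.05, 1.84-fold, limma adjusted p = 0.00414), and Adam19, which encodes a membrane-bound metalloprotease (log2 fold change -0.76, SE 0.05, 1.70-fold, limma adjusted p = 0.0119). Ak8 and Adam19 were lower on 3 of 3 vimentin-deficient arrays than on every wild-type array. At an unadjusted limma p under 0.05 there were 1072 genes, where 672 are expected by chance. A per-gene test without shared variances called 0 genes after adjustment, as did limma without any single wild-type array, and limma without vimentin-deficient replicate 2 called 1.

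The genes with the smallest p in each direction did not pass the threshold, and several of those with higher values are induced by interferon. Oas3, a sensor of viral double-stranded RNA, had a log2 fold change of 1.51 (SE 0.19, limma adjusted p = 0.138). Oas1a, of the same family, had 0.96 (SE 0.11) and Usp18, a negative regulator of interferon signalling, 1.99 (SE 0.28, limma adjusted p = 0.166). Ifi35 had 0.88 (SE 0.09, limma adjusted p = 0.124) and Ifi27l2a 0.68. Outside that group, the stress-inducible Nupr1 had 0.97, the surface protein Cd24a 1.30, the adhesion molecule L1cam 0.49, the co-stimulatory ligand Cd86 0.59 and Pald1 0.40. Among genes with lower values, Gpr34, a lysophospholipid receptor, had -1.42 (SE 0.20, limma adjusted p = 0.166), and Itgax, which encodes integrin CD11c, had -0.88 (SE 0.13). Slc9a9 had -0.69, Mocos -0.55, Slc12a2 -0.43, Tmem202 -0.43, Matk -0.35 and Zmat1 -0.33. For each of these 18 genes all 3 vimentin-deficient arrays lay beyond all 3 wild-type arrays, as did 15.5% of all tested genes, where chance gives 10%.

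One vimentin-deficient array stood apart from all others. Replicate 3 correlated with the others across probe sets at 0.975 to 0.979, while the other 5 correlated with each other at 0.992 to 0.998. Against the mean of the other two vimentin-deficient arrays, 230 genes were over 1 log2 unit lower on it and 126 over 1 log2 unit higher, while 12 genes differed by that much between vimentin-deficient replicates 1 and 2. Proliferation genes were low on this array: the difference from the mean of the other 2, in log2 units, was -3.66 for Pclaf, -3.44 for Birc5 and -2.90 for Mki67, and 22 of 29 cell cycle genes lay over 1 log2 unit below it. Sterol synthesis enzymes were low as well, with Idi1 at -3.37, Fdps at -3.16 and Sqle at -3.13. MHC class II genes were high, with H2-Eb1 at 4.11, H2-Aa at 4.07, Cd74 at 3.54 and H2-Ab1 at 3.11, as was Fxyd2 at 4.10. The chemokine gene Ccl2 was at -3.47. These are values of a single array without a test.

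Without this array, 176 genes rose and 139 fell in vimentin-deficient macrophages (limma adjusted p below 0.05, 2 arrays against 3), and with quality weights that give it a weight of 0.226, 52 rose and 41 fell, all 93 among the 315. Of the 12 largest rises, 6 were of genes in the interferon list described next: Ifit2 at 1.68 (SE 0.11), Usp18 at 1.67, Ifit1 at 1.61, Ifit3 at 1.51, Oas3 at 1.31 and Oasl2 at 1.31. Ly6e rose by 1.95 (SE 0.19) and Rtp4 by 1.41. Slco4a1, an organic anion transporter gene, rose by 1.81 on the log2 scale, Clec4e, the C-type lectin Mincle, by 1.48, Ccl2 by 1.37 and Cd24a by 1.34. The size of some rises depended on the probe set. With 6 arrays a second probe set read 0.60 against 2.34 for Ly6e, 0.63 against 1.73 for Rtp4 and 0.53 against 1.25 for Clec4e. For Slco4a1 the second read more, 3.14 against 2.48. The 12 largest falls included the monoacylglycerol lipase gene Mgll (-1.67, SE 0.15), the fatty acid-binding protein gene Fabp4 (-0.97) and the apolipoprotein gene Apoe (-0.96). Gpr34 (-1.31), the V-ATPase subunit gene Atp6v0d2 (-1.18), the macrophage survival gene Cd5l (-1.14), Adgre5 (-1.04), the beta-glucan receptor gene Clec7a (-1.03), Itgax (-1.01), Ighm (-0.96), Gadd45a (-0.89) and the myeloid transcription factor gene Cebpa (-0.87) made up the rest. Of the 315 genes, 193 lay beyond all wild-type arrays in the same direction on the left-out array. On that array Ccl2 lay below its wild-type mean, and Adgre5, Clec7a, Apoe, Gadd45a and Cebpa did not lie below all wild-type arrays. Another split of the same 5 arrays, wild-type replicates 2 and 3 against the rest, called 308 genes, 38 of them among the 315. Both splits set wild-type replicates 2 and 3 against vimentin-deficient replicates 1 and 2, so shared genes are expected. The count by genotype was thus close to that of a split by something else.

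Interferon response genes were higher as a group. Of the 26 measured members of this list, fixed before the data were examined, all 26 had higher means in vimentin-deficient macrophages, with a median log2 fold change of 0.94. The largest values were those of Ifit2 (2.20, SE 0.42), Ifit3 (2.13, SE 0.50) and Ifit1 (2.06, SE 0.36), which encode antiviral RNA-binding proteins, and of Usp18 (1.99). Bst2, an antiviral membrane protein gene, had 0.59 (SE 0.08), and Irf7, the transcription factor that amplifies the response, 1.37 (SE 0.22). Adjusted over all genes 0 members passed, and adjusted over the list alone 25 passed. The mean of the list lay 0.74, 0.84 and 1.65 log2 units above the wild-type mean on vimentin-deficient replicates 1, 2 and 3, and between -0.11 and 0.09 on the wild-type arrays. The list rose by camera with its preset correlation between genes of 0.01 (adjusted p = 1.19e-33), but not with the correlation estimated from the data, where adjusted p = 0.45 with an estimated correlation, and not by fry (adjusted p = 0.21), which asks whether a list's genes move one way without comparing them with other genes. Without vimentin-deficient replicate 3 the list passed fry (adjusted p = 0.037) and camera with the preset correlation (adjusted p = 7.78e-43), with adjusted p = 0.30 with an estimated correlation. In that fit the median was 0.65, 22 members rose adjusted over all genes and 25 adjusted over the list alone, and Irf1 alone was lower, at -0.17.

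**Figure D2:**
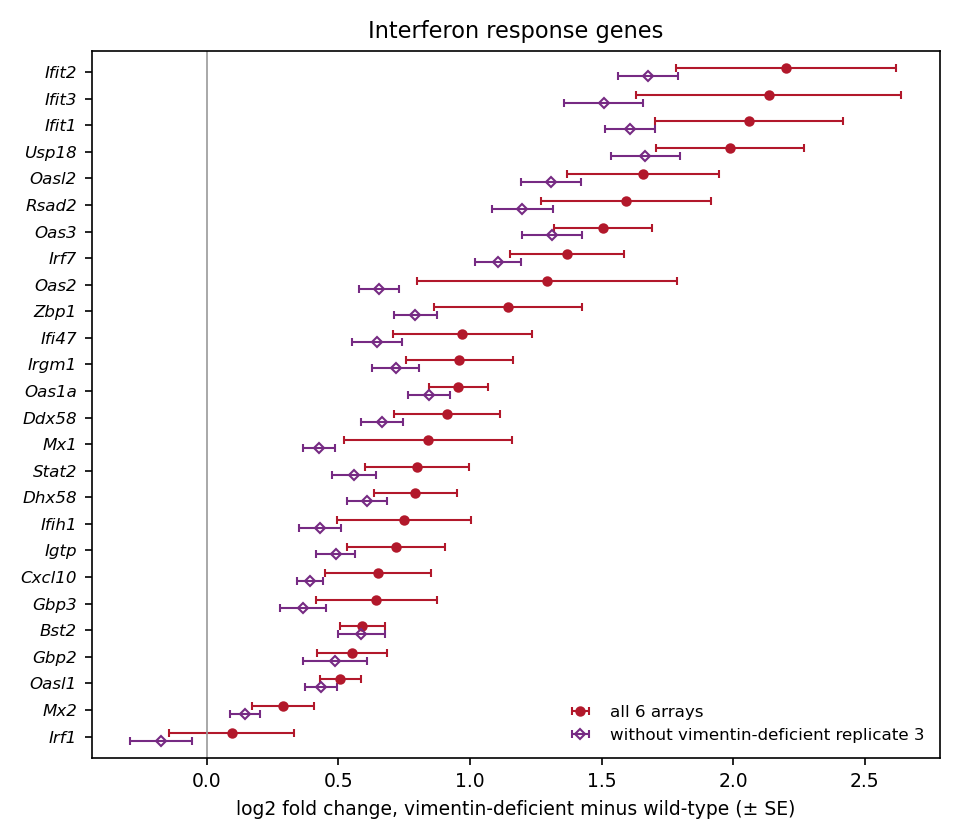
Log2 fold change of the 26 measured interferon response genes, vimentin-deficient minus wild-type, with its standard error, from limma on all 6 arrays (circles) and on the 5 arrays without vimentin-deficient replicate 3 (diamonds). With 6 arrays the values run from 0.09 for Irf1 to 2.20 for Ifit2, and only Irf1 is below 0 without replicate 3.

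Scavenger receptor and lipid uptake genes were lower as a group. Of 17 measured members 13 were lower, with a median log2 fold change of -0.14. The members with the smallest p were the endocytic receptor genes Stab2 (-0.64, SE 0.12) and Stab1 (-0.74, SE 0.14), the haemoglobin scavenger receptor gene Cd163 (-0.35, SE 0.11) and Fabp4 (-0.74, SE 0.22). Cd36 and Scarb1 had -0.54 (SE 0.23) and -0.47 (SE 0.21). Without vimentin-deficient replicate 3 Cd36 had -0.29, Scarb1 -0.23 and Cd163 -0.23, none of them past the threshold, and Stab2 (-0.77), Stab1 (-0.58) and Fabp4 (-0.97) fell. Adjusted over all genes 0 members passed, and adjusted over the list alone 2 fell, Stab1 and Stab2. The mean of the list was -0.21, -0.22 and -0.24 on the 3 vimentin-deficient arrays and between -0.05 and 0.03 on the wild-type arrays. The list fell by camera (adjusted p = 0.00515), with adjusted p = 0.44 with an estimated correlation, and by fry (adjusted p = 0.014). By fry 0 lists passed without vimentin-deficient replicate 1 or 2 and without wild-type replicate 1 or 3, and 1 list passed without wild-type replicate 2. Without vimentin-deficient replicate 3 the scavenger receptor list passed fry (adjusted p = 0.037).

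The other 5 lists that passed camera with the preset correlation had smaller shifts or shifts on single arrays. NF-kappaB targets and inflammatory cytokines rose (17 of 22 higher, median log2 fold change 0.12, camera adjusted p = 0.00515, adjusted p = 0.44 with an estimated correlation), with Ccl5 at 0.74 (SE 0.20), Cxcl10 at 0.65 (SE 0.20) and the inhibitor gene Nfkbia at 0.43 (SE 0.14). Cxcl10 is also in the interferon list. The list was 0.20, 0.20 and 0.06 above the wild-type mean on the vimentin-deficient arrays, and wild-type replicate 1 read 0.07. The NF-kappaB call was lost with the 60th percentile filter (camera adjusted p = 0.0874), and without vimentin-deficient replicate 3 the median was 0.04 with 13 of 22 higher (camera adjusted p = 0.00331, adjusted p = 0.32 with an estimated correlation), while Ccl5 had 0.48, Cxcl10 0.39 and Nfkbia 0.28. Unfolded protein response genes rose (15 of 20 higher, median 0.09, camera adjusted p = 0.000567, adjusted p = 0.70 with an estimated correlation), with Ddit3, which encodes the stress transcription factor CHOP, at 0.82 (SE 0.13). This call was lost without vimentin-deficient replicate 1 (median 0.03, camera adjusted p = 0.123). Replicate 3 lay at -0.10, below the wild-type arrays. Antioxidant and NRF2 target genes rose (15 of 21 higher, median 0.18, camera adjusted p = 0.00565, adjusted p = 0.45 with an estimated correlation), with Gstp1 at 0.61 (SE 0.21) and Txnrd1 at 0.56 (SE 0.20), while Gstm1 had -0.34 (SE 0.08). Without vimentin-deficient replicate 3 the median of the list was 0.105 (camera adjusted p = 0.0862), with Gstp1 at 0.41 and not past the threshold. In that fit 0 members rose and 1 fell adjusted over all genes, Gstm1 (-0.37, limma adjusted p = 0.0397).

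The last 2 of these lists rested on vimentin-deficient replicate 3. All 17 measured cholesterol synthesis genes were lower, with a median log2 fold change of -0.80 (camera adjusted p = 0.00397, adjusted p = 0.98 with an estimated correlation). Their mean was -0.02 and -0.14 on replicates 1 and 2 and -2.03 on replicate 3, and the median without that array was -0.10 (camera adjusted p = 0.0715). MHC class II and antigen presentation genes were higher for 13 of 15 members (median 0.18, camera adjusted p = 0.000567, adjusted p = 0.70 with an estimated correlation), with list means of -0.05, 0.06 and 1.16 on replicates 1, 2 and 3 and a camera adjusted p of 0.53 without replicate 3. In that list 2 members passed adjusted over the list alone, Cd86 and the peptide transporter gene Tap1 (0.35, SE 0.09). With 6 arrays, 0 members of each of the 5 lists passed adjusted over all genes. Adjusted over the list alone, 1 unfolded protein response gene passed and 0 in the other 3. The remaining 32 of 39 lists did not pass, with camera adjusted p from 0.0558 to 0.997. Counts of lists were as large under 7 of the other 9 splits of the 6 arrays, up to 16 lists, so the number 7 by itself does not separate the genotypes.

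**Figure D3:**
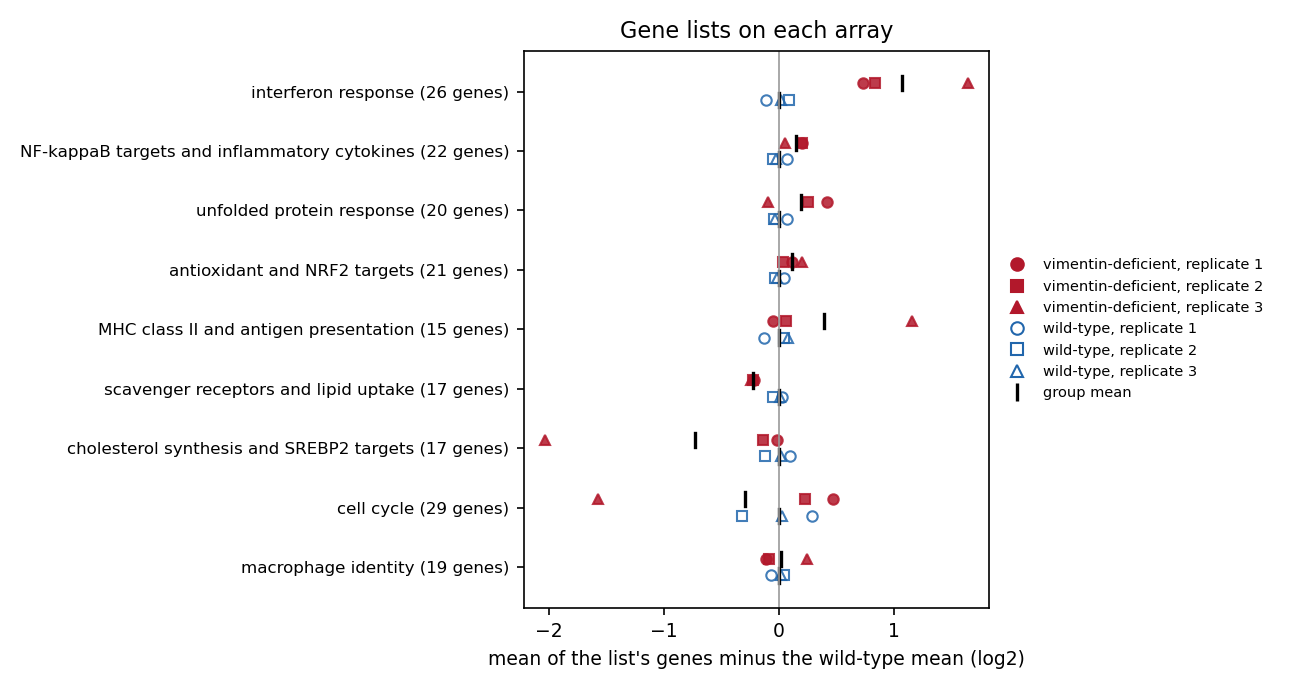
Mean of the measured genes of 9 lists on each array, relative to the mean of the 3 wild-type arrays (log2), with group means as vertical bars. The interferon response list separates the genotypes most widely, the scavenger receptor list has 3 vimentin-deficient arrays between -0.24 and -0.21, and the cholesterol synthesis and cell cycle lists are displaced on vimentin-deficient replicate 3, to -2.03 and -1.57.

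With vimentin-deficient replicate 3 left out, 10 lists passed camera with the preset correlation and 0 with an estimated one. Among the 10, actin cytoskeleton and motility genes rose (23 of 28 higher, median 0.05, camera adjusted p = 0.00716). Glucose transport and glycolysis genes rose too (16 of 21 higher, median 0.08, camera adjusted p = 0.0417), where the median with 6 arrays was -0.02. Besides the interferon list, unfolded protein response genes rose (median 0.20, camera adjusted p = 2.94e-09, adjusted p = 0.56 with an estimated correlation), with 5 members up and 1 down adjusted over all genes and 7 up and 1 down adjusted over the list alone. Asns rose by 1.29 and Trib3 by 1.06 on the log2 scale, both targets of the ATF4 branch, and Atf4 itself by 0.70. PPAR gamma target and lipid droplet genes fell (all 15 lower, median -0.12, camera adjusted p = 0.000156, adjusted p = 0.30 with an estimated correlation). That list also passed fry (adjusted p = 0.037), with Fabp4 and Pparg (-0.47, SE 0.08) past the threshold. Lysosome and autophagy genes fell too (19 of 21 lower, camera adjusted p = 0.000275, adjusted p = 0.56 with an estimated correlation), with Atp6v0d2, Lgmn (-0.40) and Tfeb (-0.36). Cell cycle genes rose as a list (27 of 29 higher, median 0.37, camera adjusted p = 2.05e-10, adjusted p = 0.61 with an estimated correlation) with 0 members past the threshold over all genes and 1 adjusted over the list alone. With all 6 arrays that median was -0.23, and without vimentin-deficient replicate 1 instead the list fell (median -0.62, camera adjusted p = 0.00348, adjusted p = 0.78 with an estimated correlation), so its direction depended on the array left out. The cell cycle list also varied within the wild-type arrays, from -0.32 on replicate 2 to 0.29 on replicate 1.

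Read-outs usual for macrophages in atherosclerosis did not pass the threshold with 6 arrays. Of the 14 genes fixed beforehand, 11 were tested. The lipid uptake receptor gene Cd36 had a log2 fold change of -0.54 (SE 0.23, limma adjusted p = 0.625) and Msr1, a scavenger receptor, -0.18 (SE 0.21). The cholesterol exporter genes Abca1 and Abcg1 had -0.17 (SE 0.25) and 0.43 (SE 0.29). The cytokine genes Tnf and Il1b had 0.07 (SE 0.06) and 0.10 (SE 0.15), Ccl2 had 0.21 (SE 0.94), the glucose transporter gene Slc2a1 0.19 (SE 0.13), the haem oxygenase gene Hmox1 -0.21 (SE 0.11), the oxidase subunit gene Cybb 0.14 (SE 0.20) and the mannose receptor gene Mrc1 -0.64 (SE 0.36). Several of these moved without vimentin-deficient replicate 3: Mrc1 to -0.18, Cd36 to -0.29, Msr1 to -0.01, Il1b to -0.08 and Cybb to -0.06, none of them past the threshold. In the same fit, Ccl2 rose to a log2 fold change of 1.37 (limma adjusted p = 0.0307) and Abca1 fell, at -0.47 (limma adjusted p = 0.0173).

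Markers of macrophages and of other cells that marrow cultures can hold did not pass as lists in 1 direction with 6 arrays. By the mixed version of fry, which counts changes in both directions, dendritic cell markers and B cell and plasma cell markers passed (adjusted p = 0.0047 for each), as did 1 other list, actin cytoskeleton and motility (adjusted p = 0.016). Adjusted over the dendritic cell list alone, 1 member rose, Bst2 (0.59), and 1 fell, Itgax (-0.88). Bst2 is also in the interferon list. Irf8, another bright dendritic cell marker, had -0.16 (SE 0.26). The macrophage identity list had a median log2 fold change of -0.06 over 19 genes, with Lyz2 at -0.06 (SE 0.08) and Ctss at 0.05 (SE 0.10). Its median was -0.13 without vimentin-deficient replicate 3, with 14 of 19 members lower (camera adjusted p = 0.0715), Lyz2 at -0.15 and Ctss at -0.06. With 6 arrays, medians were -0.04 for neutrophil markers, -0.01 for dendritic cell markers, -0.09 for T cell and NK cell markers, -0.02 for fibroblast and stromal markers, -0.04 for monocyte and immature myeloid markers, 0.03 for osteoclast markers, -0.04 for mast cell and basophil markers, 0.02 for endothelial markers and -0.06 for adipocyte markers. Erythroid and megakaryocyte markers were lower for all 8 members (median -0.08, camera adjusted p = 0.0558, and 0.106 without vimentin-deficient replicate 3), with Pf4 at -1.02 (SE 0.63) and Epor at -0.25 (SE 0.08). Without that array Pf4 had -0.22 and Epor -0.32 (limma adjusted p = 0.0389). B cell and plasma cell markers had a median of -0.10 over 5 genes (camera adjusted p = 0.0558), with Ighm at -1.32 (SE 0.29) and Cd22 at -0.44 (SE 0.09), both past the threshold adjusted over the list alone. Of the other Ighm probe sets above the filter, 1 had -1.24, 1 had -0.04 and 2 had 0.12 and 0.02. The B cell list fell without vimentin-deficient replicate 3 (camera adjusted p = 0.00809, adjusted p = 0.56 with an estimated correlation). In the same fit the median of osteoclast markers was -0.07, with 8 of 10 lower (camera adjusted p = 0.0991, fry adjusted p = 0.043).

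Genes near Vim were compared because a targeted locus can keep flanking DNA of the donor strain. Within 10 Mb of Vim on chromosome 2, 0 of 61 tested genes passed, against 2 of 13307 elsewhere (two-sided Fisher's exact p = 1), and without vimentin-deficient replicate 3 it was 3 of 61, Fam107b, Slc39a12 and Usp6nl, against 311 of 13307 (odds ratio 2.16, 95% interval 0.431 to 6.70, Fisher's exact p = 0.172). Ak8 lies within 20 Mb of Vim, and with that window 1 of 252 genes passed against 1 of 13116 (Fisher's exact p = 0.0373, 95% interval of the odds ratio 0.663 to 3940, which includes 1). Its direct protein-coding neighbour Spaca9 also fell without vimentin-deficient replicate 3 (log2 fold change -0.69, limma adjusted p = 0.00380), and without that array 7 of 252 genes passed against 307 of 13116 (Fisher's exact p = 0.671).

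RNA quality was read from control transcripts measured at both ends. The 3' minus 5' difference of the Actb control probe sets was 0.21 ± 0.02 (SD, n = 3) in vimentin-deficient and 0.19 ± 0.01 (SD, n = 3) in wild-type samples (exact two-sided permutation p = 0.3), and for Gapdh the group difference was 0.00022 (exact permutation p = 1). For Tfrc it was 1.39 ± 0.04 against 1.52 ± 0.04 (SD, n = 3 each, exact permutation p = 0.1), the smallest p that 3 against 3 samples can give, and for Pcx 0.76 ± 0.13 against 0.70 ± 0.04 (SD, n = 3 each, exact permutation p = 0.6). Vimentin-deficient replicates 2 and 3 had the highest values of the 18S ribosomal RNA 5' control, 9.37 and 9.34, against 6.98 to 8.04 on the other arrays. The labels give no sex. Xist was above the filter on all 6 arrays, and the 9 Y-linked probe sets read at most 6.47, below the expression filter of 6.93. All 3 Xist probe sets read highest on vimentin-deficient replicate 3, the brightest at 11.89 against 10.68 to 11.14 on the other arrays.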

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

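Quantile normalization, median centring, the filters, the probe set rules, eBayes without trend or with robust estimation, and the other thresholds left the counts of genes within 1.5 times of 0 higher and 3 lower and kept Vim past the threshold. The median of all genes moved by at most 0.035 log2 units from 0 in any setting. Array quality weights gave 52 genes higher and 41 lower. The per-gene test gave 0 lower and a Vim log2 fold change of -5.89 with adjusted p = 0.29, where each gene's own variance from 6 values was used. The replicate number as a block gave 0 lower genes and -5.89 for Vim with adjusted p = 0.062. The labels do not say that the numbers pair the samples. Deviations of same-numbered arrays from their group means correlated at 0.50, -0.19 and 0.055, and not every sample correlated best with its own number. Vimentin-deficient replicate 3 shifts its group mean and so weighs on all deviations of that group. These correlations therefore cannot show whether samples were paired. The block spends degrees of freedom, so the calls it lost do not tell whether an effect is weaker. The block gave 10 lists. Leaving out 1 array in turn gave 0 to 176 genes higher and 0 to 139 lower, with Vim from -6.28 to -5.66 and 7 to 11 lists.

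Lists past the threshold numbered 11 with the mean of a gene's probe sets, 17 with all probe sets separately, where probe sets of 1 gene count as separate members, 12 without probe sets ending in _x_at or _s_at, 11 with array quality weights, 1 with fry and 0 with an estimated correlation. The scavenger receptor list passed camera with the preset correlation in all 15 settings and the interferon list likewise. The cell cycle list reversed, from a median log2 fold change of -0.225 to 0.216 with array quality weights and 0.366 without vimentin-deficient replicate 3, since that array lies far below the others. Over the fits without 1 array the cell cycle median ran from -0.624 (without vimentin-deficient replicate 1, camera adjusted p = 0.00348) to 0.366. Both directions were called with the preset correlation, and neither with an estimated one (camera adjusted p = 0.78 and 0.61). Over the fits without 1 array 0 to 5 lists passed fry. Over the named genes other than Vim, 2535 values kept direction and call, 74 gained a call, 13 lost it, 44 changed sign without a call on either side and 0 reversed. Vim, counted apart, kept its direction throughout and lost its call with the per-gene test, with the block and without each wild-type array in turn. For lists these numbers were 456, 48, 7, 67 and 2. Genes near Vim gave Fisher's exact p = 0.0373 with a 20 Mb window, where Ak8 enters as the only call in the window and the interval of the odds ratio (0.663 to 3940) includes 1. Other causes were not tested. Offsets for linear values were not run because the table is log2, and the settings of the gene-level variance model have no value for camera. A fit without both vimentin-deficient replicate 3 and wild-type replicate 1 was tried after seeing the splits and is not reported, because wild-type replicate 1 had been picked for its likeness to the vimentin-deficient arrays, which enlarges the difference by construction.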

Other observations

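The split of 5 arrays that set wild-type replicates 2 and 3 against wild-type replicate 1 and vimentin-deficient replicates 1 and 2 called 308 genes, 38 of them shared with the split by genotype. Wild-type replicates 2 and 3 had lower values of the cell cycle genes Ccnd1 (-0.86 on the log2 scale, limma adjusted p = 0.0104), Ccne2 (-0.89), Rrm2 (-0.85) and Hells (-0.98), but a higher value of the centromere gene Cenpa (0.56), and higher values of Pik3ip1 (0.84), Dbp (1.06), a clock output gene, and the pro-apoptotic gene Bcl2l11 (0.71). It called 6 members of the cell cycle list and 0 of the interferon list, where the split by genotype called 0 and 22. Relative to the wild-type mean, the cell cycle list was at -0.32 on wild-type replicate 2 and 0.03 on replicate 3. It was at 0.29 on wild-type replicate 1 and at 0.47 and 0.23 on vimentin-deficient replicates 1 and 2. The list mean was thus lower on both wild-type replicates 2 and 3 than on the rest, but on replicate 3 it lay much closer to them.

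The tests on the wrong label, RNA degradation, the contribution of replicate 3 to the interferon list, an exposure outside the genotype and the splits of 5 arrays were chosen after the results were seen. With 10 splits of 3 against 3 arrays, the real one included, no share under 0.05 can be reached. By genotype 3 genes passed, and the highest other split gave 0, so 1 split of 10 reached the real count. For lists, 8 of 10 splits reached 7, with 16 as the highest other. For the absolute median of the interferon list 1 of 10 did, at 0.935 against 0.533 as the highest other. Without vimentin-deficient replicate 3, 1 of 10 splits reached 315 genes, with 308 as the highest other, so the count by itself does not separate genotype from other structure in these samples.

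Vimentin-deficient replicate 3 stood apart by low cell cycle and sterol synthesis genes and high MHC class II and interferon response genes, while Vim argues against a wrong genotype label, since it lay at least 5.51 log2 units below the lowest wild-type array on all 3 probe sets. RNA degradation is argued against by Tfrc and Pcx, whose 3' minus 5' difference lay below the highest of the other 5 arrays (-0.21 for the one that came closest), though those of Actb (by 0.024) and Gapdh (by 0.0048), which the bound (set after the data were seen) left out, lay above it. Replacement of most macrophages by cells without their markers is argued against by the macrophage identity list. Its median was 0.32 log2 units higher than on the other 2 vimentin-deficient arrays. Partial replacement, or replacement by myeloid cells that share these markers, was not tested. The median of the 8 dendritic cell markers tested, of 15 fixed beforehand, moved by 0.0062 and so met the recorded bound. The filter on the mean of 6 arrays can remove a marker raised on 1 array alone. This median therefore cannot decide on an admixture of dendritic cells. Single markers rose (Irf8 by 0.89, Itgax by 0.37), and a small admixture was not tested. The bound for this median was recorded before the test, but for an array already seen to stand apart. A different state of this culture or animal, such as less proliferation or exposure to interferon, may account for this array. Malat1 was also 2.77 log2 units higher on it, and all 3 Xist probe sets read highest there. A technical difference of this sample was not tested, and the design has no group to test either possibility.

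Interferon response genes were higher on all 3 vimentin-deficient arrays. Replicate 3 alone does not account for this, since the median without it was 0.65, and neither do cis effects of donor DNA around Vim, since 0 of 26 members lie within 20 Mb of it. The position of the members cannot tell whether donor DNA acts on genes elsewhere. An exposure of the vimentin-deficient animals or cultures outside the genotype, such as an infection or a shared culture day, could give the same picture: the lowest vimentin-deficient array lay 0.65 log2 units above the highest wild-type array, which both explanations predict. No label gives litters, days or cages, so exposure and genotype cannot be told apart. That loss of vimentin raises interferon signalling in macrophages stays a hypothesis.

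Ak8 was lower, and lies on the same chromosome as Vim. A sequence variant of the donor strain under its probe set may be the cause, but 0 other Ak8 probe sets were above the filter, so this stays open. Donor DNA around Vim as a source of several calls was tested in the 10 Mb window, where Fisher's exact p = 0.172 without vimentin-deficient replicate 3, with an interval of the odds ratio that includes 1, so it stays open too. The neighbouring Spaca9, picked after its value was seen, was also lower without vimentin-deficient replicate 3. Donor DNA that reaches Ak8 could cover Spaca9 too, with variants under both probe sets, so this does not decide the question.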
